A study of Mus musculus with 3 samples.

How the data were processed

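Droplet-based 3' single-cell RNA sequencing (10x Genomics Chromium Next GEM) had been run on sorted mouse CD8 T cells. P14 cells carry a transgenic receptor for the GP33 peptide of LCMV and came from mice with a TCF-1-GFP reporter; naive P14 cells were given to C57BL/6 mice 8 days after B16.Gp melanoma cells. TdLN and PBMC cells were collected on day 16 after transfer and sorted as CD45.1+ CD44+ CD8 T cells. Memory cells were collected on day 200 after acute LCMV infection and sorted for CD45.1, CD44 and CD127 (IL-7 receptor), among other markers, without KLRG1, so Klrg1 and Il7r are set in part by that gate. The tissue of the memory cells and the number of mice per library are not stated. A library of tumour-infiltrating cells is named in the study design and was not analysed here. 1 library per group was used, 3 in all.

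The deposited values are whole-number UMI counts per gene and cell barcode, not normalized, made by the authors with Cell Ranger 3.1.0 on the mm10 genome, per the submitters' processing notes. The barcodes had already been called as cells: 7503 for TdLN, 6165 for PBMC and 8321 for memory, with 72062695, 49592338 and 72283532 counts. All 31053 genes were read, and 30934 gene IDs were found in GENCODE M21 (GRCm38, the same assembly as mm10), which gave the coordinates. Reads had been counted at the 3' end, so no isoform, allele of Ptprc (CD45.1 or CD45.2) or full receptor sequence can be read from the values. V segment UMIs are the few that reach the 5' part of the transcript.

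Cells with at least 500 genes and at most 10% mitochondrial counts were kept: 6265, 5652 and 7003. The mitochondrial limit removed 15.9% of the TdLN, 6.26% of the PBMC and 14.9% of the memory barcodes. Kept cells had medians of 9674, 7085 and 9956 UMIs. Clustering used log values of counts per 10000, 2000 genes most variable within libraries, 30 principal components and 15 nearest neighbours (scikit-learn 1.9.0). Leiden resolution 0.8 (leidenalg 0.10.2) was applied to a graph weighted by shared neighbours. The 3 libraries were clustered together and without batch integration. Ribosomal, mitochondrial, receptor and immunoglobulin segment genes, Xist and Y-linked genes were left out of the variable genes. Cluster markers were fixed before the data were examined, as were the 17 gene lists, the comparisons, the rule for named genes and most alternative settings. The rule that turns markers into names was set after the clusters had been seen: at least 3 markers and 33.3% of those measured at least 1.5-fold above the other cells. Names end in -like because they rest on markers alone. Clusters named B-like (77 TdLN cells), erythroid or platelet-like (173 PBMC cells) and macrophage, monocyte or dendritic-like (112 TdLN cells) were left out, with the few cells of the other libraries in them. No cluster was named for CD4 T cells, gamma delta T or NK cells, neutrophils, melanoma cells or stromal cells. Scrublet scoring (scanpy 1.11.5) marked 0, 11 and 0 cells, too few to have worked, so doublets were not removed. An alternative removed the 314, 256 and 392 cells with the highest scores.

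Counts were summed over the T cells of each library and divided by their total (CPM). With 1 library per group there is no estimate of variation between animals, so no p-value is given. Each CPM has an exact Poisson 95% interval, each ratio an exact conditional binomial 95% interval and each share a Clopper-Pearson 95% interval (scipy 1.17.1), which cover counting error only. A count of 0 in the summed T cells allows up to 0.0438 CPM in TdLN, 0.0630 in PBMC and 0.0428 in memory (3 counts). Genes with at least 20 CPM in the higher library were compared, and a ratio of at least 2-fold either way was counted. Both comparisons with memory share the memory library, so genes high or low in both are not independent observations. Named genes are the 8 highest and 8 lowest ratios among genes with at least 50 CPM in the higher library, without ribosomal, mitochondrial, predicted, receptor segment, haemoglobin, Xist and Y-linked genes, plus a panel of 12 genes, 1 of which is not reported here, and up to 4 members of each list. Genes outside that rule, among them Gm42418 and the V segments, were chosen after their values were seen. For each list with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size, matched in 20 bins of mean expression, as a description of these libraries.

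For shares of cells with a UMI, each cell was thinned to 4200 UMIs and shallower cells were left out. The ratios were tested on simulated data with 100 genes at 2.5-fold and 100 at 5-fold. The simulated counts were Poisson draws around set levels. They test the calculation under counting error only, not variation between cells, animals or libraries. All were recovered as at least 2-fold in each of the 3 comparisons (4625 genes in TdLN over memory, 4385 in PBMC over memory, 4583 in TdLN over PBMC), no unchanged gene was called, and the intervals covered the true ratio for 95.2%, 94.8% and 95.0% of the genes. Of 200 random lists of 15 genes, 5%, 2.5% and 6.5% fell outside the middle 95%, and all did after 1 was added to their log2 ratios. Alternatives were no cell filter, a stricter one (1000 genes, 5% mitochondrial counts), all cell types, doublet removal, no cycling clusters, TMM scaling (edgeR 4.0.16), totals without ribosomal and mitochondrial genes, equal weight per cell, thinned cells, minimums of 100 CPM or 10 counts, 10 matching bins, means, another thinning depth, and Leiden resolutions 0.4 and 1.2, 20 principal components, clustering without cell cycle genes and each library alone. Added after seeing the data were leaving out the effector T-like clusters, keeping only T cells with a Trbv13-3 UMI (1451 TdLN, 1005 PBMC and 3131 memory cells), and clustering without the 389 genes at least 2-fold apart between libraries. The 2 planned comparisons of a memory T-like class within TdLN were not run: 23 TdLN cells were in that class, and none when TdLN was clustered alone; they were not run either on the 199 TdLN cells of the class in the last clustering, which had left out genes these comparisons would read. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used.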

Results

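Single-cell RNA sequencing of P14 cells, mouse CD8 T cells with a transgenic receptor for the GP33 peptide of lymphocytic choriomeningitis virus (LCMV), was compared in 3 libraries. The cells came from the tumour-draining lymph node (TdLN) or the blood (PBMC) of mice with B16.Gp melanoma, a melanoma line made to express the viral glycoprotein, on day 16 after transfer, or were memory cells of day 200 after an acute LCMV infection. After filtering, 6076 TdLN, 5479 PBMC and 6993 memory T cells held 68497588, 47602982 and 70037956 UMI counts. Each group had 1 library, so no test between groups was possible, and tissue, day, sort gate and preparation cannot be separated. Values are CPM, the count of a gene relative to all counts of the summed T cells, with 95% intervals in parentheses that cover counting error only.

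The 3 libraries held different mixtures of T cell clusters. Clusters with raised effector markers, among them the granzyme genes Gzma and Gzmb, held 54.2% (52.8–55.5) of PBMC T cells, 1.99% (1.67–2.34) of memory cells and 0.165% (0.07895–0.302) of TdLN cells. Clusters with raised Cd69, Egr1, Fos and Dusp1, named recently activated T-like, held 69.8% (68.6–70.95) of TdLN T cells and 0.183% (0.0876–0.335) of PBMC T cells. These genes follow receptor triggering, but Fos and Dusp1 are also on the dissociation and AP-1 stress list. The markers Nr4a1, Egr2, Irf8 and Tnfrsf9 did not pass in these clusters, which also takes at least 20 CPM. A cluster with raised Tcf7, Slamf6, Tox, Id3, Cd200 and Ikzf2, named precursor exhausted T-like, held 14.3% (13.4–15.2) of TdLN, 3.23% (2.78–3.73) of PBMC and 0.0143% (0.000362–0.0796) of memory cells. Pdcd1, Xcl1, Cxcr5 and Tnfrsf4, the other markers behind that name, did not pass in it. The cluster with raised Ccr7, Klf2 and Lef1, named memory T-like, held 27.9% (26.7–29.1) of PBMC T cells but 23 TdLN cells and 11 cells of the memory library itself. Igfbp4, Ccr7 and Actn1, among its leading genes, are on the naive T cell list, so the name need not mean memory cells. The memory markers Il7r, Tcf7, S1pr1, Bcl2 and Ltb did not pass in it. Cycling cells made up 6.12% (5.53–6.75) of TdLN, 0.548% (0.3697–0.781) of PBMC and 0.458% (0.313–0.645) of memory T cells, and interferon-responding cells 8.66% (7.96–9.39), 1.24% (0.965–1.57) and 1.64% (1.36–1.97). No cluster was named exhausted T-like when the libraries were clustered together, but with each library clustered alone 14.9% of PBMC and 1.51% of memory cells were. Each of these names rested on 4 of 12 markers: Tox, Lag3, Entpd1 and Cxcr6 in PBMC, and Tox, Cxcr6, Ccl3 and Ccl4 in memory. Pdcd1 and Havcr2 passed in neither. S100a4, Lgals3 and Gzmk, among the leading genes of the PBMC cluster, also led an effector T-like cluster of the joint clustering. Of the memory cells, 95.7% (95.1–96.1) lay in clusters without a name under the markers, and most clusters were drawn mainly from 1 library, so a cluster may stand for that library and not for a cell type. Clustering each library alone, where markers are raised against cells of the same library only, gave other shares: recently activated T-like cells were 4.01% of TdLN, effector T-like cells 9.01% of TdLN and 39.3% of PBMC, cycling cells 5.19% of TdLN and 4.34% of PBMC, and interferon-responding cells 4.90% of PBMC. At the lower clustering resolution no TdLN or PBMC cell was in a precursor exhausted T-like cluster, 19.9% of TdLN cells were in interferon-responding clusters and 42.9% of PBMC cells in memory T-like clusters. At the higher resolution 0.183% of PBMC cells were precursor exhausted T-like, and alone none was. Clustered without genes 2-fold apart between libraries, an alternative added after seeing the data, 199 TdLN cells were memory T-like.

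**Figure D1:**
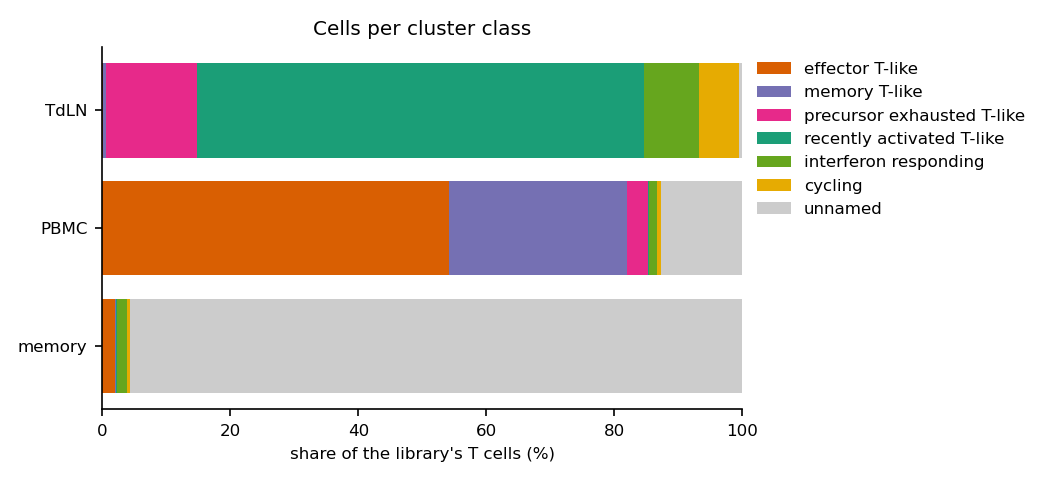
Share of T cells (%, horizontal axis) per cluster class (colours) in the TdLN, PBMC and memory libraries (bars, 1 library each). Effector T-like clusters fill 54.2% of the PBMC bar, recently activated T-like clusters 69.8% of the TdLN bar, and clusters without a name 95.7% of the memory bar.

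The P14 receptor joins the beta chain V segment Trbv13-3 (chromosome 6, 41130147 to 41130585) to an alpha chain V segment of the Trav14 family, so segment counts bear on how far each library held the sorted clone. Of beta chain V segment UMIs, 4.48% (3.95–5.06) were not Trbv13-3 in memory T cells, 10.8% (9.497–12.2) in TdLN T cells and 31.4% (29.4–33.5) in PBMC T cells. In the PBMC library the other segments lay mainly in the effector T-like clusters, where they made up 72% (68.3–75.5) of 625 beta V UMIs, against 13.6% (11.8–15.5) of 1421 in the remaining PBMC T cells. Trbv15 held 19.2%, Trbv19 11.0%, Trbv12-2 10.9% and Trbv29 8.8% of the beta V UMIs of these effector T-like cells. A Trbv13-3 UMI was seen in 5.36% (4.58–6.23) of the PBMC effector T-like cells, at a median of 5275 UMIs per cell, and in 33.7% (31.8–35.6) of the remaining PBMC T cells, at a median of 12316 UMIs. In TdLN, 6.49% (2.14–14.5) of 77 B-like cells had such a UMI, at a median of 4593 UMIs. A Trbv13-3 UMI need not mark a P14 cell at such a share, though the background of PBMC was not measured. In cells where Trbv13-3 was the only beta segment seen, the Trav14 family made up 46.4% (35.5–57.6) of 84 alpha V UMIs in the PBMC effector T-like clusters, 77.5% (74.4–80.3) in the remaining PBMC T cells and 89.1% (88.1–90.1) in memory; in PBMC effector T-like cells with other beta segments alone it made up 29.0% (21.7–37.1). In cells with other beta segments alone it made up 43.4% (32.1–55.3) in the remaining PBMC T cells, 57.1% (46.3–67.5) in TdLN and 84.0% (75.6–90.4) in memory, so a UMI of another beta segment does not by itself mark a cell outside the clone. The 139 effector T-like cells of the memory library had mostly Trbv13-3, with 12.7% (5.27–24.5) of 55 beta V UMIs from other segments. In the remaining memory T cells that share was lower, at 4.395% (3.87–4.97). A Trbv13-3 UMI was seen in 25.2% of these effector T-like cells and 45.2% of the remaining memory T cells. Their medians were 5672 and 10019.5 UMIs per cell. Of the constant region genes, Trac and Trbc2 stood at 601 and 2233 CPM in the PBMC effector T-like cells and 339 and 1293 CPM in the remaining PBMC T cells, and Trbc1 at 483 and 611 CPM. These receptor values were looked up after the gene results had been seen.

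**Figure D2:**
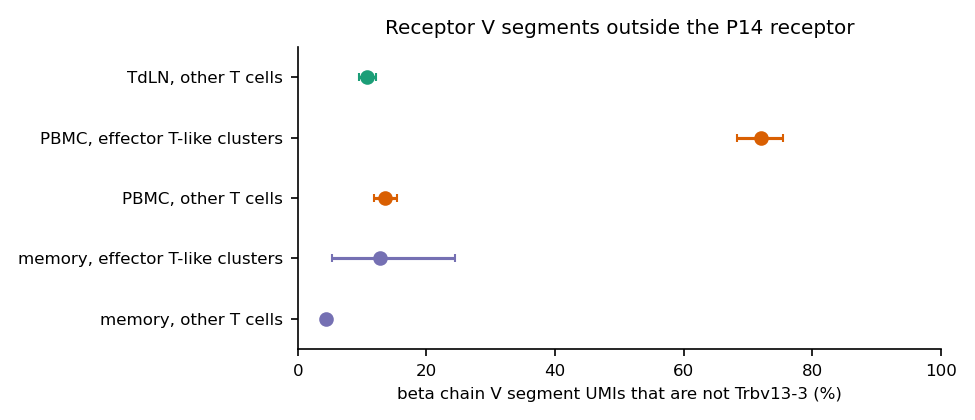
Share of beta chain V segment UMIs that are not Trbv13-3 (%, horizontal axis) in effector T-like clusters and in other T cells of each library (points, 1 library each; bars, 95% Clopper-Pearson intervals). The PBMC effector T-like clusters stand at 72.0%, all other groups drawn at 13.6% or less; the 10 TdLN cells in effector T-like clusters had no beta V UMI and are not drawn.

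TdLN cells had more RNA of naive-cell, immediate early and division genes, and less of cytotoxic genes, than day 200 memory cells. Igfbp4 (chromosome 11, 99041244 to 99054392), an insulin-like growth factor binding protein on the naive T cell list, reached 92.2 CPM in TdLN and 0.5997 CPM in memory, 154-fold higher (114–214). Id3 (chromosome 4, 136143497 to 136145755), an inhibitor of E protein transcription factors, was 62.7-fold higher (54.3–72.7), and the AP-1 subunit Fos (chromosome 12, 85473890 to 85477273) was 24.1-fold higher (22.01–26.4). Ccl5 (chromosome 11, 83525778 to 83530518), a chemokine that memory CD8 T cells make in large amounts, stood at 752 CPM in TdLN and 12505 CPM in memory, 16.6-fold lower (16.5–16.8). Of 4625 genes with at least 20 CPM in either library, 183 were at least 2-fold higher in TdLN and 88 at least 2-fold lower; with TMM scaling the split was 146 and 125. The median log2 ratio of all genes was 0.16 with total counts and 0.03 with TMM, so small ratios should be read against that shift.

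Among the other genes with the largest ratios, the division genes Ube2c, Birc5, Pclaf and Top2a were 91.96-fold, 45.1-fold, 32.7-fold and 12.5-fold higher in TdLN, and Dapl1, a member of the naive T cell list, was 14.5-fold higher (13.97–15.01). Lower in TdLN were the calcium-binding proteins S100a6, 16.5-fold lower (16.1–16.9), and S100a4, 9.61-fold lower (9.15–10.1), and the chemokine receptor Ccr2, 11.00-fold lower (9.897–12.3). Camk2n1, an inhibitor of a calmodulin-dependent kinase, was 32.01-fold lower (26.9–38.4), Lars2, the mitochondrial leucyl-tRNA synthetase, 22.5-fold lower (21.8–23.2), and the histone genes Hist1h4d and Hist1h1e 12.5-fold and 8.07-fold lower. Histone genes outside the naming rule went both ways: Hist1h1c was 4.11-fold lower in TdLN, but Hist1h2ap and Hist1h2ae were 6.30-fold and 2.63-fold higher. Gm42418, a predicted gene outside the naming rule, was lower in TdLN as well: it held 0.0752% of the T cell counts in TdLN, 2.47% in PBMC and 3.79% in memory.

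By gene list, 17 of 17 measured cell cycle members were higher in TdLN than in memory, 15 of them at least 2-fold, with a median log2 ratio of 3.64; Ccnb2 was 110.1-fold higher (70.3–183). With equal weight per cell the median was 1.61 over 10 members, and without the cycling cluster too few members were measured for a median. All 15 measured type I interferon response members were higher, 8 at least 2-fold (median 1.05), among them Ifi27l2a at 8.24-fold higher (8.05–8.43) and Ifit1 at 3.92-fold higher (3.64–4.24). Of 17 stem and memory genes, 5 were at least 2-fold higher and 1 was at least 2-fold lower (median 0.44). Myb, a transcription factor of progenitor cells, was 84.1-fold higher (54.3–138) at 24.02 CPM in TdLN, and Slamf6 was 3.45-fold higher (3.29–3.62). Tcf7 (chromosome 11, 52252371 to 52283014), which encodes TCF-1, was 1.61-fold higher (1.58–1.65). Il7r, which encodes the CD127 that the memory sort required, was 2.78-fold lower (2.73–2.82) in TdLN. Of 12 cytotoxic effector genes, 8 were at least 2-fold lower and 1 was at least 2-fold higher (median -1.67); Gzmk was 8.400-fold lower (7.45–9.51), Fasl 5.51-fold lower (4.92–6.19) and Gzmb 3.72-fold lower (3.37–4.11). Of 8 NK receptor genes, 6 were at least 2-fold lower (median -2.26); Klrk1 was 6.06-fold lower (5.85–6.28) and Klrc1 5.91-fold lower (5.56–6.29). Of 11 naive T cell genes, 5 were at least 2-fold higher and none was at least 2-fold lower (median 0.76), and of 16 dissociation and AP-1 stress genes 7 were at least 2-fold higher and 1, Hspa1b, was at least 2-fold lower (median 0.89). Junb was 4.77-fold higher (4.68–4.87) and Dusp1 10.3-fold higher (9.47–11.2). All 7 measured T cell receptor response genes were higher (median 0.57), with Egr1 at 9.53-fold higher (8.33–10.9) and Cd69 at 6.05-fold higher (5.86–6.24).

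Tissue residency genes went both ways in TdLN over memory: 4 of 8 were at least 2-fold higher, such as Itgae at 12.01-fold higher (10.02–14.5), and 2 were at least 2-fold lower, with Itga1 at 51.8-fold lower (38.6–71.2) (median 0.80). Of 14 circulation and lymph node homing genes, 2 were at least 2-fold lower and 1 was at least 2-fold higher (median -0.44); Itga4 was 5.95-fold lower (5.66–6.27) and Ccr7 2.64-fold higher (2.56–2.73). Of 13 glycolysis genes, 11 were higher, only Pkm at least 2-fold (median 0.44). Against 10000 random lists matched on expression, these lists stood at or above the 98.9th percentile, apart from the cytotoxic effector, NK receptor, and circulation and lymph node homing lists at percentile 0. Within the middle 95% of the random lists were oxidative phosphorylation (median 0.12), cytokine receptor (0.15), chemokine and cytokine (0.16), MHC class I presentation (0.04) and cytosolic ribosomal protein genes (0.04); with TMM the medians of all but the chemokine and cytokine list had the other sign. Only 3 of 18 inhibitory receptor and exhaustion genes were measured, too few for a percentile: Ctla4 was 30.6-fold higher (23.5–40.6), Tox 8.16-fold higher (7.25–9.21) and Cd160 1.09-fold higher (1.04–1.14). Below the minimum, Lag3 and Pdcd1 were low in level in TdLN but higher there than in memory. Lag3 stood at 12.4 CPM in TdLN and 0.1999 in memory, and Pdcd1, which encodes PD-1, at 3.23 and 0.685. Havcr2, which encodes TIM-3, was near the floor in both, at 0.219 and 0.129. With the stricter cell filter, the stem and memory list stood at percentile 90 and the T cell receptor response list at 97.2; with 100 CPM the stem and memory list stood at 92.5. By its mean of 0.34, the tissue residency list stood at percentile 66.03.

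**Figure D3:**
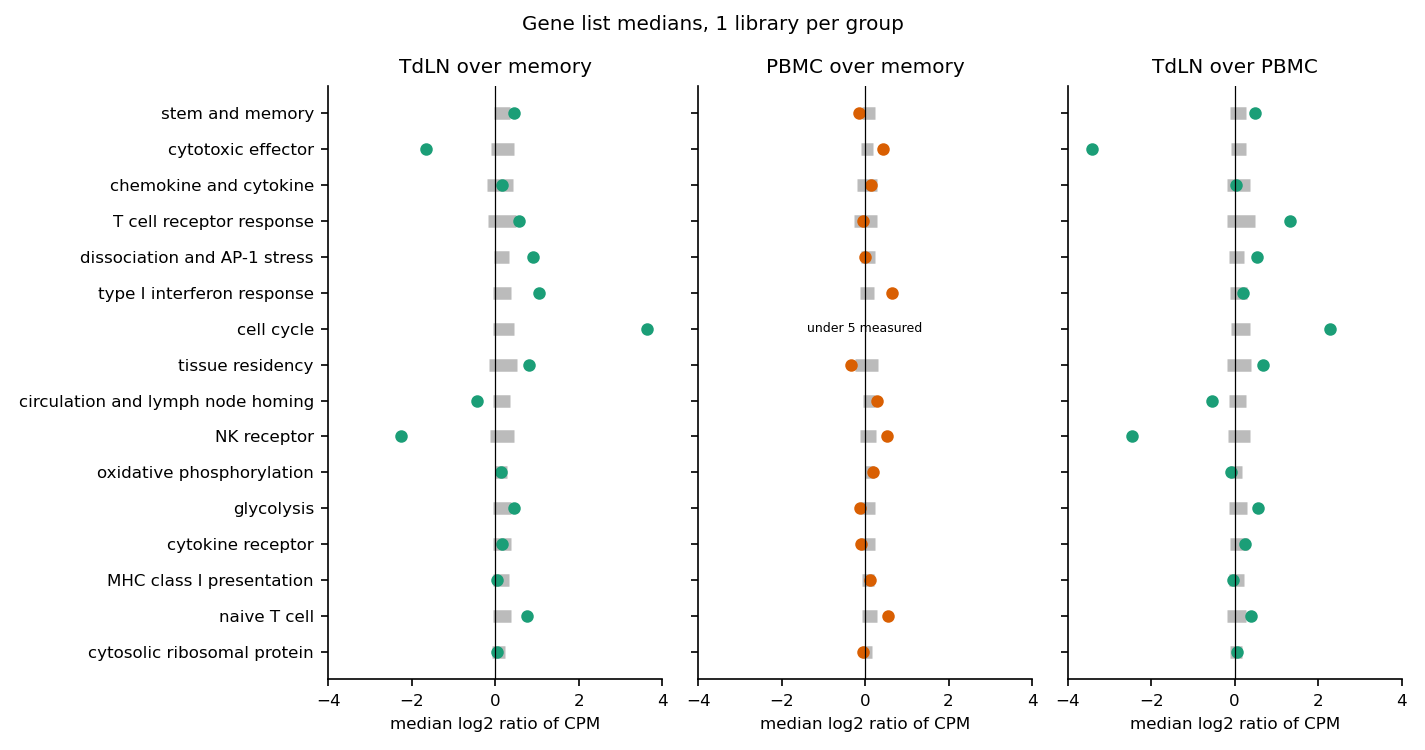
Median log2 ratio of CPM of the measured members of each gene list (points) in the 3 comparisons (panels, 1 library per group); grey bars span the middle 95% of 10000 random lists matched on expression. In TdLN over memory the cell cycle list stands at 3.64 and the NK receptor list at -2.26.

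Several effector genes were far higher in PBMC than in memory. Gzma (chromosome 13, 113093825 to 113100981), which encodes granzyme A, reached 1287 CPM in PBMC and 7.72 CPM in memory, 167-fold higher (153–182). Cx3cr1 (chromosome 9, 119901616 to 120069879), the fractalkine receptor of circulating effector cells, was 32.2-fold higher (28.4–36.6), and Zeb2 (chromosome 2, 44983632 to 45117395), a transcription factor of terminal effector cells, 7.96-fold higher (7.44–8.52). Klrg1 (chromosome 6, 122270596 to 122282882), an inhibitory lectin-like receptor, was 12.2-fold higher (10.9–13.6), but the memory cells had been sorted as KLRG1-negative. Klrg1 was raised together with Gzma, Gzmb, Cx3cr1 and Zeb2 in the largest effector T-like cluster. The gate may therefore also lower these genes, and the effector T-like share, in memory, which was not tested. Without the effector T-like clusters, an alternative added after seeing the data, the log2 ratio of Zeb2 turned to -0.21 and that of Klrg1 was 0.41. Gzma at 7.85, against 7.38 in all T cells, and Cx3cr1 at 2.75 stayed at least 2-fold higher. The clusters were left out of memory too, with 139 memory cells, and Gzma and Cx3cr1 were among their markers. These ratios therefore do not show how much of the PBMC level lay in the clusters. Zeb2 and Klrg1 are among the markers that named these clusters, so their fall was largely set in advance. The effector T-like clusters are those where 72.0% of beta chain V segment UMIs were not those of the P14 receptor. Of 4385 genes, 73 were at least 2-fold higher in PBMC and 27 at least 2-fold lower; with totals that leave out ribosomal and mitochondrial genes, the split was 105 and 78.

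Naive-cell and interferon genes were also higher in PBMC than in memory. Igfbp4 was 94.1-fold higher (69.4–131), Dapl1 7.24-fold higher (6.97–7.52), the lectin-like receptor gene Klre1 25.6-fold higher (22.2–29.7) and the interferon-induced Ifi27l2a 7.23-fold higher (7.06–7.41). Ccr7, the receptor that guides cells into lymph nodes, was 2.86-fold higher (2.76–2.96), Slamf6 2.31-fold higher (2.19–2.43) and Tox 4.44-fold higher (3.905–5.06), while Tcf7 was 1.15-fold higher (1.12–1.18). Among the genes eligible for naming by size, with at least 50 CPM in the higher library, the lowest ratios were those of Ier3 at 2.61-fold lower (2.43–2.81), Il7r, a gated gene, at 2.45-fold lower (2.41–2.499), and the oxysterol receptor gene Gpr183 at 2.43-fold lower (2.34–2.54). Cd7, Crtam, Wdr89, Stap1 and Gpr65 were 2.29-fold, 2.26-fold, 2.09-fold, 1.99-fold and 1.92-fold lower. Pdcd1 stood at 2.96 CPM, Havcr2 at 1.47, Lag3 at 8.44 and Mki67, a division marker, at 6.68 CPM in PBMC, against 2.17 CPM for Mki67 in memory.

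Of 16 cytotoxic effector genes, 7 were at least 2-fold higher in PBMC than in memory and none was at least 2-fold lower (median 0.42, percentile 100); Gzmb was 5.99-fold higher (5.698–6.297). Of 10 NK receptor genes, 2 were at least 2-fold higher (median 0.52, percentile 100), and of 16 circulation and lymph node homing genes 4 were, such as S1pr5, a receptor for egress from tissue, at 4.57-fold higher (4.18–4.996) (median 0.28, percentile 99.4). Type I interferon genes were higher in 13 of 14 members (median 0.63, percentile 100) and naive T cell genes in 9 of 11 (median 0.54, percentile 100). Stem and memory genes were higher in 7 and lower in 8 of 15 members (median -0.15, percentile 0.29), and tissue residency genes higher in 3 and lower in 4 of 7 (median -0.34, percentile 0.605), with Xcl1, a chemokine, at 5.98-fold lower (5.32–6.74) and Bhlhe40 at 3.99-fold higher (3.62–4.405). Without the effector T-like clusters, an alternative added after seeing the data, the medians changed sign. Cytotoxic effector genes stood at -1.33, NK receptor genes at -1.22, circulation and lymph node homing genes at -0.36 and stem and memory genes at 0.40. At least 2-fold lower were then 104 genes in place of 27. Effector markers had named these clusters, so the fall of cytotoxic and NK receptor genes was largely set in advance. In T cells with a Trbv13-3 UMI the medians were -0.60 for cytotoxic effector, -0.57 for NK receptor and 0.32 for stem and memory genes. Circulation and lymph node homing genes stood at -0.178 there, at percentile 5.635 and so within the random range. In that setting 79 genes were at least 2-fold lower. Other settings moved some lists into the random range: stem and memory to percentile 5.36 with totals that leave out ribosomal and mitochondrial genes, 46.9 with 10 counts and 74.8 by the mean, NK receptor to 12.0 and circulation to 93.1 with 100 CPM, and circulation to 97.2 without the cell filter. Tissue residency stood at percentile 62.7 with those totals and 15.2 by the mean, and its median turned to 0.49 with 10 counts, but it was -1.37 without the effector T-like clusters and -1.44 in T cells with a Trbv13-3 UMI, both at percentile 0. In these 2 settings the chemokine and cytokine median was -1.79 and -0.73, at percentiles 0 and 0.05, against 0.14 within the random range in all T cells.

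**Figure D4:**
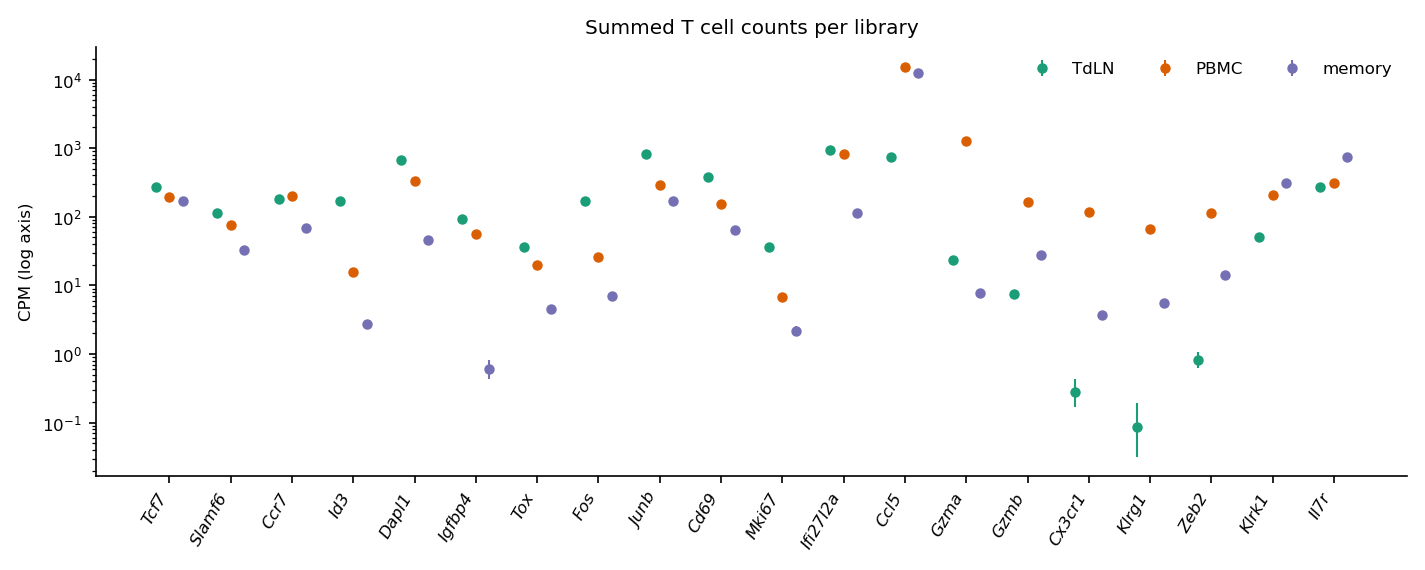
Summed T cell counts in CPM (vertical log axis) of 20 named genes (horizontal axis) in the TdLN, PBMC and memory libraries (colours, 1 library each); bars are exact Poisson 95% intervals. Gzma stands at 1287 CPM in PBMC against 23.7 in TdLN and 7.72 in memory, and Id3 at 171 CPM in TdLN against 15.6 and 2.73.

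TdLN and PBMC cells, both of day 16, differed in division, immediate early, cytotoxic and NK receptor genes, among others. Id3 was 10.98-fold higher (10.2–11.8) in TdLN than in PBMC, Fos 6.59-fold higher (6.21–6.99), Fosb, another AP-1 subunit, 4.39-fold higher (4.06–4.75), and Zfp36, which encodes an mRNA decay factor, 3.72-fold higher (3.53–3.92). The division genes Pclaf, Birc5, Ube2c and Top2a were 17.1-fold, 12.5-fold, 10.5-fold and 4.85-fold higher in TdLN; without the cycling cluster Top2a had a log2 ratio of -0.15 and Mki67 of -0.98. Klrg1, for which neither of these libraries was gated, stood at 0.0876 CPM in TdLN (6 counts) and 66.9 CPM in PBMC, and Cx3cr1 at 0.277 and 118 CPM. Of 4583 genes, 123 were at least 2-fold higher in TdLN and 88 at least 2-fold lower, with a split of 95 and 113 by TMM; the median log2 ratio of all genes was 0.11 with total counts and -0.01 with TMM.

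Zeb2 was 139.5-fold lower (107–185), Gzma 54.3-fold lower (51.7–57.1), Lgals3, which encodes galectin-3, 28.2-fold lower (25.02–31.96), Klre1 27.8-fold lower (23.9–32.4), Gzmb 22.3-fold lower (20.4–24.4) and S100a4 21.2-fold lower (20.2–22.2) in TdLN than in PBMC. Of 16 cytotoxic effector genes, 13 were at least 2-fold lower in TdLN (median -3.42), as were 7 of 9 NK receptor genes (median -2.45) and 7 of 15 circulation and lymph node homing genes (median -0.55), and each list stood at percentile 0. The PBMC level of these genes again came with the 72.0% of other beta V segments in the effector T-like clusters, and without these clusters 23 genes in place of 88 were at least 2-fold lower in TdLN. The medians were then -0.13 for cytotoxic effector and -0.50 for NK receptor genes, a shift largely set in advance, since effector markers had named these clusters. In T cells with a Trbv13-3 UMI these were -2.27 and -1.24. All 7 T cell receptor response genes were higher in TdLN, 4 at least 2-fold (median 1.32), with Egr1 at 13.3-fold higher (11.01–16.2). Of 17 cell cycle genes, 15 were at least 2-fold higher (median 2.28), and of 15 dissociation and AP-1 stress genes 6 were (median 0.54). Glycolysis genes were higher in 12 of 13 members (median 0.56), with Tpi1 at 1.82-fold higher (1.71–1.94), and tissue residency genes in 6 of 8 (median 0.69), with Xcl1 at 7.29-fold higher (6.49–8.21); these 5 lists stood at the 99.99th percentile or above. Stem and memory genes were higher in 12 of 17 members (median 0.48) and naive T cell genes in 9 of 11 (median 0.40), but in T cells with a Trbv13-3 UMI these medians were 0.17 and 0.02, at percentiles 46.6 and 9.90. Without the effector T-like clusters these percentiles were 5.54 and 3.31, and with 100 CPM 97.3 and 96.8. Without the cycling cluster the cell cycle median was -0.05, at percentile 30.2, and with equal weight per cell it was 1.02. Type I interferon genes were within the random range (median 0.19), but at percentile 99.6 with equal weight per cell, 99.4 with thinned cells, 98.9 with 10 counts and 99.4 by the mean. Tcf7 was 1.405-fold higher (1.37–1.44), Slamf6 1.49-fold higher (1.44–1.56), Tox 1.84-fold higher (1.704–1.98) and Lag3 1.47-fold higher (1.302–1.66) in TdLN; the ratio of Pdcd1, 1.09-fold higher (0.878–1.36), has an interval that includes 1.

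At the level of single cells thinned to 4200 UMIs, Tcf7 was seen in 64.8% (63.6–66.1) of TdLN, 42.8% (41.5–44.2) of PBMC and 50.9% (49.7–52.1) of memory T cells, and Slamf6 in 30.9%, 20.99% and 12.4%. Tox was seen in 13.3%, 7.25% and 1.76%, and Tcf7 together with Tox in 8.74%, 3.44% and 0.878%, against 8.64%, 3.11% and 0.894% if the 2 were independent. Gzmb was seen in 0.952% of TdLN, 35.03% of PBMC and 7.85% of memory cells, Cx3cr1 in 0.0668%, 33.6% and 1.29%, and Ccr7 in 51.3%, 32.9% and 23.4%. Il7r was seen in 59.3%, 51.6% and 90.7%, the memory cells having been sorted for its protein. Pdcd1 was seen in 0.835%, 1.402% and 0.357%, and Pdcd1 together with Havcr2 in 0 of 5987 TdLN cells, against 5 of 6076 without thinning. Without thinning, Tcf7 was seen in 88.4%, 55.96% and 76.5%, Gzmb in 1.68%, 41.2% and 13.6%, and Tox in 30.1%, 12.5% and 4.15%. The B-like cells of TdLN, at a median of 4593 UMIs against 9744, 7122 and 9957 for the T cells of the 3 libraries, give the background of the TdLN library; that of the other 2 was not measured. Thinned to 2100 UMIs, 6.67% of 75 B-like cells had a Tcf7 UMI, 8% Il7r and 2.67% (0.325–9.30) Tox, and none had Gzmb, Cx3cr1 or Pdcd1, which allows up to 4%. At that depth the TdLN, PBMC and memory T cells had 42.2%, 25.1% and 30.1% for Tcf7, 6.902%, 3.82% and 0.993% for Tox, and 0.629%, 0.738% and 0.158% for Pdcd1, and TdLN had 0.778% for Gzmb and 0.0331% for Cx3cr1. In TdLN, Pdcd1, Gzmb and Cx3cr1 thus lie below what 75 B-like cells can resolve, and Tox lies above their share but within its interval. Slamf6 and Ccr7 were seen in 18.7% and 17.3% of the B-like cells, a cell type that can express them. Thinning left out 89 TdLN, 486 PBMC and 271 memory T cells.

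**Figure D5:**
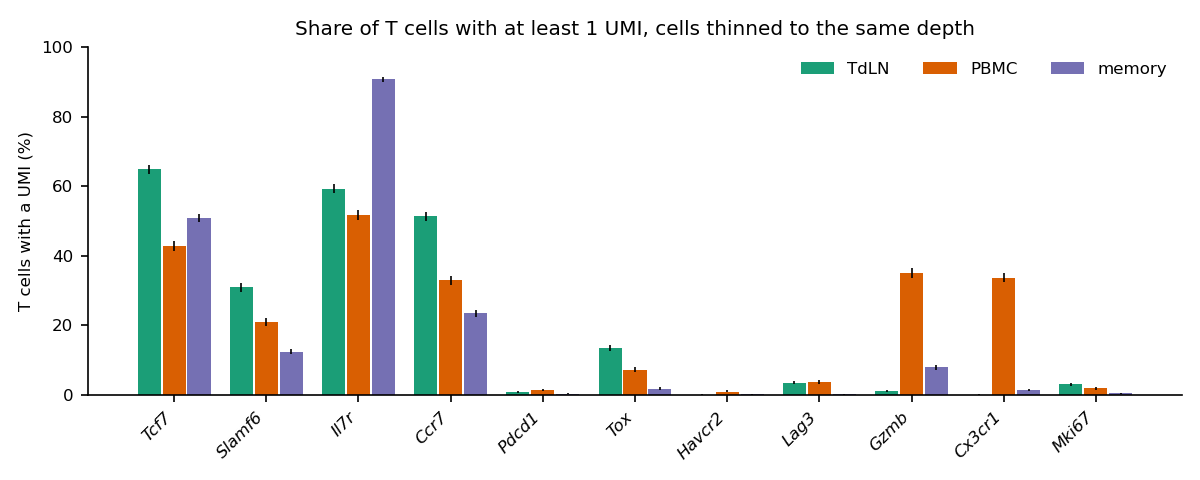
Share of T cells with at least 1 UMI (%, vertical axis from 0) of 11 panel genes (horizontal axis) in the TdLN, PBMC and memory libraries (colours, 1 library each), cells thinned to 4200 UMIs; bars are 95% Clopper-Pearson intervals. Gzmb is seen in 35.03% of PBMC and 0.952% of TdLN cells, Tcf7 in 42.8% and 64.8%.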

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

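The tests of heat shock genes, of the beta chain in the PBMC effector T-like clusters, of Trbv13-3 in the effector T-like cells of memory and of free RNA were chosen only after the result was seen, as were the use of cells with a Trbv13-3 UMI, of their alpha segments and of single other cell types for Gm42418.

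UMIs of beta V segments other than Trbv13-3 made up 31.4% of beta V UMIs in PBMC and 10.8% in TdLN against 4.48% in memory, and in PBMC they lay with the effector genes. The PBMC effector T-like clusters exceeded the remaining PBMC T cells by 58.4 percentage points in other beta segments and by 41.9 points in alpha segments outside the Trav14 family, so these clusters may hold many T cells without the P14 receptor that passed the CD45.1 sort. A loss of Trbv13-3 with the effector state is argued against by its 5.75-fold higher level in the effector T-like cells of memory than in those of PBMC, and free RNA as the source of their Trbv13-3 by its fold of 0.265 over the remaining PBMC T cells, against 0.0168 for Ccr7 and 0.0114 for Dapl1. Trbv13-3 stood at 60.5 CPM in the effector T-like and 75.1 in the remaining T cells of memory, and at 10.5 and 39.7 in PBMC. Part of the 5.75-fold thus lies between the libraries as a whole. The memory value rests on 48 Trbv13-3 UMIs in 139 cells, sorted without KLRG1. Whether cells without the P14 receptor are the whole cause cannot be told: in T cells with a Trbv13-3 UMI 3 of 5 genes (Klrg1 at 3.45-fold, Cx3cr1 at 9.72-fold, Gzma at 56.5-fold) were over 2-fold higher in PBMC than in memory by their lower limits, the outcome set as evidence against, but only 46.4% of alpha V UMIs in such cells of the effector T-like clusters were of the Trav14 family, so many of them need not be P14 cells. The sort of the memory cells without KLRG1 may also raise these ratios over memory and was not tested. For the naive T cell list in TdLN, only the beta chain argues against cells without the P14 receptor. The excess of other beta segments over memory was 6.32 points in TdLN, under the 10 needed. Alpha segments outside Trav14 were 26.7% in TdLN against 14.5% in memory, a wider gap for which no limit had been set. The list median over memory in TdLN was 0.75 in T cells with a Trbv13-3 UMI and 0.76 in all T cells. These medians cannot decide, since such a UMI was seen in 6.49% of B-like TdLN cells and only 23.9% of TdLN T cells. The filter may therefore keep cells without the P14 receptor. In PBMC the excess of other beta segments over memory was 26.9 points, the outcome set beforehand as evidence for such cells. The PBMC list median was 0.73 in T cells with a Trbv13-3 UMI and 0.54 in all T cells. This cannot decide, since the setting leaves out most effector T-like cells. A Trbv13-3 UMI was seen in 5.36% of those and 33.7% of the remaining PBMC T cells.

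AP-1 and immediate early genes were higher in TdLN than in memory in 10 of 10 measured members of the stress list, with a median log2 ratio of 1.35. For handling stress that raises heat shock genes too, the 6 heat shock members had a median of -0.22 and a highest value, for Hspa8, of 0.25. A median under 0 was the outcome set as evidence against it. Memory itself stood apart, however, with Hspa1b and Hspa1a at 31.3 and 17.4 CPM. They stood at 0.380 and 0.482 CPM in TdLN and 0.714 and 0.756 CPM in PBMC. A low ratio over memory therefore cannot show that TdLN cells were unstressed. An excess carried only by the recently activated T-like clusters is argued against, since the median fold was 2.17 in the T cells outside them. Handling that induces immediate early genes, with or without heat shock genes, stays open. So does receptor signalling in the node, which the design confounds with tissue and day.

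Gm42418 (chromosome 17, 39846958 to 39848788), which overlaps ribosomal RNA sequence, held 0.0752% of TdLN T cell counts against 2.47% in PBMC and 3.79% in memory. A difference that acts on every cell of the TdLN library, such as its preparation, would lower it in each class: in the 6 comparisons of T cell classes its level in TdLN was at most 0.0459 times that of the other library. A state of the node's T cells alone is argued against: cells of other types showed a fold of 0.0496, TdLN over the other libraries together, and although the types differed between libraries, B-like cells alone had a fold of 0.0273 and macrophage-like cells 0.0124, TdLN over memory, with each of the 3 and 5 memory cells above every TdLN cell of its type. A library-wide cause may also lie behind part of the lower Lars2, Camk2n1, Hist1h4d and Hist1h1e in TdLN, which was not tested for these genes; the tissue itself stays open.

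Clusters named for other cell types were found after the CD8 sort. B-like cells made up 1.23% of the filtered TdLN cells, against 0.0428% in memory, but 1.15% and 1.34% when each library was clustered alone. Macrophage, monocyte or dendritic-like cells made up 1.79% of the filtered TdLN cells, against 0.0714% in memory. Cells named erythroid or platelet-like made up 3.06% of the filtered PBMC cells, against 0.0286% in memory, and held Cd3e at 396 CPM, so many of them need not be of another type.

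Some lists and genes lay above memory in TdLN and below it in PBMC, or the other way round. These differences between the ratios over memory, TdLN minus PBMC on the log2 scale, were not tested. The difference was 0.59 for stem and memory, -2.10 for cytotoxic effector, 1.14 for tissue residency, -0.71 for circulation and lymph node homing, -2.77 for NK receptor and 0.56 for glycolysis genes. It was -4.48 for Gzmb and -8.73 for Cx3cr1. Without the effector T-like clusters the PBMC medians over memory were 0.40 for stem and memory and -1.33 for cytotoxic effector genes. They were -0.36 for circulation and lymph node homing and -1.22 for NK receptor genes, so the opposite signs of these 4 lists ended. Gzmb stood at 0.01, while Cx3cr1 at 2.75 and tissue residency genes at -1.37 kept their signs. Effector markers, Gzmb among them, had named these clusters, so the fall of cytotoxic and NK receptor genes was largely set in advance. The glycolysis median in PBMC was -0.05 at percentile 63.6 without these clusters and 0.04 with equal weight per cell.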

How the results depend on the processing

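Leaving out the effector T-like clusters, keeping only T cells with a Trbv13-3 UMI, and clustering without genes 2-fold apart between libraries were chosen after seeing the data. Of 1452 alternative values of the named genes at least 2-fold apart, 1401 were still at least 2-fold, and 55 of 78 gene counts were within 1.5 times. Of 692 list medians, 623 kept their place below, inside or above the middle 95% of random lists, whatever their sign. Of 126 class shares 44 moved, 16 of 21 where each library was clustered alone. The expression minimum set the counts by its construction: with 100 CPM they were 39 higher and 25 lower in TdLN over memory, 19 and 6 in PBMC over memory and 22 and 31 in TdLN over PBMC; with 10 counts they were 1405 and 1043, 916 and 789, and 1130 and 811. Totals without ribosomal and mitochondrial genes, which let more genes pass the minimum, gave 296 higher and 149 lower in TdLN over memory, 78 lower in PBMC over memory and 225 higher in TdLN over PBMC. In TdLN over PBMC, equal weight per cell gave 150 lower, thinned cells 134 lower and leaving out cycling clusters 72 higher genes, the last with Mki67 at -0.98 and Top2a at -0.15; the cause of the first pair was not tested. Without the effector T-like clusters, lower genes numbered 104 in PBMC over memory and 23 in TdLN over PBMC, and with Trbv13-3 cells alone 79 and 37. In PBMC over memory these settings turned the stem and memory median to 0.40 and 0.32. Cytotoxic effector genes turned to -1.33 and -0.60, and NK receptor genes to -1.22 and -0.57. Circulation and lymph node homing turned to -0.36 without the clusters and to -0.178, within the random range, with Trbv13-3 cells. A minimum of 10 counts turned tissue residency to 0.49; the cause was not tested. Genes that turned without the clusters in PBMC over memory were Pdcd1 (-0.34), Zeb2 (-0.21), Bhlhe40 (-0.64), S1pr5 (-0.91) and Ccl4 (-1.64); with Trbv13-3 cells, Mki67 (-0.033) and Ccl4 (-0.16). In TdLN over PBMC, Bhlhe40 turned to 1.496 and 0.74 and Havcr2 to 0.76 and 0.41. The cycling share of TdLN was 5.12% at resolution 1.2, 5.17% with 20 principal components and 5.19% clustered alone; clustered alone, the effector T-like share was 39.3% in PBMC, where 14.9% took the name exhausted T-like, and 9.01% in TdLN, the recently activated T-like share of TdLN was 4.01%, and the cycling and interferon-responding shares of PBMC were 4.34% and 4.90%. The interferon-responding share of TdLN was 19.9% at resolution 0.4 and 7.21% without genes 2-fold apart, and the precursor exhausted T-like share 0% at resolution 0.4 and 15.8% with 20 principal components. The precursor exhausted T-like share of PBMC was 0.183% at resolution 1.2 and 0% at 0.4 and clustered alone, and the memory T-like class was 42.9% of PBMC at resolution 0.4 and 199 TdLN cells without genes 2-fold apart; the cause of these shifts was not tested. Of 108 shares of cells with a UMI at other depths, 91 moved beyond their interval. Depth limits Pdcd1, Havcr2 and Lag3, which are below 20 CPM in all 3 libraries, and the class comparisons within TdLN were not run for lack of cells, with 39 and 27 memory T-like cells at resolutions 0.4 and 1.2.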

Other observations

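The clusters and genes named here were chosen after their values were seen. A cluster of 117 cells, 105 of them from memory, had raised Xcl1, a chemokine for cross-presenting dendritic cells, Itga1, an integrin of tissue-resident cells, and Cd160. Of the beta V UMIs of its memory cells, 3.67% (1.01–9.13) were not Trbv13-3, and Cd8a stood at 992 CPM in them against 333 CPM in all memory T cells. The memory library, sorted as KLRG1-negative, still held 139 effector T-like cells, 1.99% (1.67–2.34), and 5.497 CPM of Klrg1.

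Memory T cells had the heat shock genes Hspa1b and Hspa1a at 31.3 and 17.4 CPM, against 0.3796 and 0.482 CPM in TdLN and 0.714 and 0.756 CPM in PBMC. The immunoglobulin gene Igkc stood at 48.1 CPM in memory T cells, 1.85 in TdLN and 4.68 in PBMC, and a cluster of 134 cells with raised Igkc and Jchain held 123 memory cells, of which 17.1% (10.9–24.9) also had a Trbv13-3 UMI. The fragment crystallizable receptor gene Fcgr2b, an inhibitory receptor of antibody complexes, was 99.9-fold lower (59.3–183) in TdLN than in memory. The erythroid or platelet-like cells of PBMC carried T cell RNA, with Cd3e at 396 CPM against 391 CPM in PBMC T cells.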
